A study of Mus musculus with 6 samples.

How the data were processed

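RNA of LSK cells (the lineage-negative, Sca1-positive, Kit-positive fraction of bone marrow, in which blood stem cells and early progenitors lie) was measured on 6 Affymetrix mouse expression arrays. Per the labels' protocols, the cells were sorted by flow cytometry from fresh bone marrow of gene therapy treated mice without a working Mpl gene on the C57BL/6J strain, RNA was extracted with a column kit for small samples and amplified before biotin labelling. The labels put 3 arrays in a control group that received a GFP vector and 3 in a group that received an Mpl vector. No label says that the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

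The deposited values are on a log2 scale and were made by the authors with RMA and the affy package, per the submitters' processing notes; versions, and any step after RMA, are not given in the sources used here. RMA corrects the background, puts the arrays on a common distribution and summarises the probes of a probe set on a log2 scale, so that a value has no separate background or detection call. Sorted values of the other arrays differed from those of GFP replicate 1 by up to 0.409, so the distributions were close without being identical. Deposited log2 values ran from 0.767 to 14.2, and the direction of every difference is Mpl minus GFP. Arrays have no read depth, and their small number is among the limits on precision.

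Of 45101 probe sets, 64 control probe sets were left out and 45037 were tested. The probe annotation used here gave 34945 of them a single gene symbol, 932 several symbols, and 9160 none. Entrez identifiers of 34741 single-symbol probe sets matched the GRCm38.p6 gene table, which changed 0 symbols. Probe sets with several symbols or none entered the test of probe sets but were named in no result. No probe set carried the symbol Mpl in this annotation, so the level of the transduced gene was not analysed here. Each of 18193 genes was represented by its probe set with the highest mean over the 6 arrays.

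Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), with Benjamini-Hochberg adjustment over all probe sets or all genes and a threshold of 0.05. The titles number the arrays 1 to 3 in both groups, and the replicate number was not a term of the model. Gene lists were written from textbook knowledge, with the tests, the rule for named genes and most of the alternatives, before the data were examined. They were 24 lists for testing and 2 lists for checking samples (sex-linked genes, and hemoglobin and mature blood RNA). Of 666 list entries 599 were measured, 3 of them under a newer symbol. An error in matching older symbols, which had assigned some entries to the wrong gene, was corrected after a first pass over the results, and 12 lists passed before and after it. The 24 lists were tested with limma's camera, a competitive test that sets a list against all other genes, with the preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, a self-contained test, were run beside it, and members were also adjusted over the list alone.

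Named genes were chosen by rule. Up to 12 genes per direction came from those past the threshold with no overlap between the groups. Places left were filled, by smallest unadjusted p, from genes with an absolute log2 fold change of at least 1, no overlap and a mean at or above the median gene, and these are given as values that did not pass. Up to 4 members of each list with the smallest unadjusted p were added, and unnamed predicted genes were left out. Agreement between arrays was measured as Pearson correlation over the tested probe sets and as principal components of the 5000 most variable ones.

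The fits were tested on simulated data, with 200 changed rows at 4 sizes in each of 20 draws that used the measured means and moderated variances. For the 18193 genes of the Mpl against GFP comparison, 74.6% of genes changed by 4 log2 units were recovered, 17.1% of those changed by 2 and 0.2% of those changed by 1, and 4.96% of calls were false on average. For the 45037 probe sets the recovered shares were 62.1%, 3.5% and 0.1%, with 5.77% of calls false. A list of independent genes raised by 1 log2 unit was called in 20 of 20 draws by camera with the preset correlation. With an estimated correlation it was called in 12 and by fry in 15, and the 23 other lists gave 3, 0 and 2 false calls over all draws. In the measured data the estimated correlation ran from 0.018 (hypoxia and glycolysis genes) to 0.763 (S phase genes) among the lists past the list test. The simulated genes were independent, so these counts do not give the rate of false calls on the measured lists. Each simulated gene also had 1 variance for both groups, while the median measured SD was 0.564 in GFP and 0.308 in Mpl. The recovered shares therefore need not hold for the measured genes. Alternatives covered a filter on low values, quantile normalization again, subtraction of array medians, cyclic loess, a trended and robust variance, array weights, the replicate number as a block, other thresholds, each array left out in turn, other ways to represent a gene, and other list tests. Alternatives chosen after the data were seen left out GFP replicates 2 and 3 together or added the mean level of T and NK cell genes as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.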

Results

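Transcript levels were measured in LSK cells of mice that lack Mpl, the receptor for thrombopoietin, after bone marrow gene therapy. The comparison asked how transfer of the Mpl gene changed the transcripts of these stem and progenitor cells. There were 3 arrays of cells given a GFP vector, the control, and 3 arrays of cells given the Mpl vector. Array medians were 4.68 on each GFP array and 4.86, 4.94 and 4.90 on Mpl replicates 1, 2 and 3, in log2 units.

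The Mpl arrays resembled each other more than the GFP arrays did. Pearson correlation over 45037 probe sets averaged 0.955 within the Mpl group, 0.840 within the GFP group and 0.879 between groups. GFP replicate 2 stood apart, with a mean correlation of 0.816 with the other arrays against 0.885 to 0.914 for the rest. The first principal component, with 50.2% of the variance, placed it at 216 and the other arrays between -59.4 and 12.5. On that array 210 genes lay below 4 log2 units while lying at 7 or more on all others, compared with 0 to 15 such genes on each other array. The median standard deviation of a gene was 0.564 in the GFP group and 0.308 in the Mpl group. The within-GFP correlation was 0.886 without GFP replicate 2. GFP replicates 1 and 3 each correlated better with every Mpl array (0.898 to 0.920) than with each other. The second principal component, with 20.2% of the variance, placed GFP replicate 1 at 111, GFP replicate 2 at 26.8 and GFP replicate 3 at -103. The Mpl arrays lay between -20.7 and -6.60 on it.

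Rnf217, which encodes a RING-type ubiquitin ligase, was the gene that passed the test between Mpl and GFP arrays. Its level rose from 2.62 ± 0.33 in GFP to 9.56 ± 0.62 in Mpl (mean ± SD in log2 units, n = 3 each), a log2 fold change of 6.94 with a standard error of 0.40 (limma, adjusted p = 0.0475). All 4 probe sets of Rnf217 were higher in Mpl, with log2 fold changes of 0.93, 3.49, 6.94 and 2.02. The GFP level of Rnf217 lay below the lower quartile of each GFP array (2.92, 3.18 and 2.87), where RMA values are mostly background, so that the size of its fold is uncertain. Leaving out GFP replicate 2 or 3 or any of Mpl replicates 1, 2 and 3 ended the call of Rnf217 (adjusted p of 0.159, 0.152, 0.216, 0.367 and 0.154), and without GFP replicate 1 it was kept (adjusted p = 0.0293), among 59 genes. The call of Rnf217 also ended with array medians subtracted (adjusted p = 0.0618), cyclic loess (0.0699 adjusted), trended and robust variance (0.0943 adjusted), array weights (0.0524 adjusted), the mean of its probe sets (0.233 adjusted) and the most variable probe set of each gene (0.0782 adjusted).

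No other gene passed, and the genes that follow are values with no overlap between the groups that missed the threshold. Higher in Mpl was Clu, the secreted chaperone clusterin, with a log2 fold change of 3.52 ± 0.39 (SE, limma adjusted p = 0.154, higher in 3 of 3 Mpl arrays). Dsg2, a desmosomal cadherin, differed by 3.77 ± 0.45 (SE, adjusted p = 0.154). The quinone reductase gene Nqo1 differed by 2.68 ± 0.37, the pore-forming protein gene Gsdme by 2.13 ± 0.30 and the adenylate kinase gene Ak1 by 4.52 ± 0.66 (SE). Morrbid, a long noncoding RNA linked to the survival of short-lived myeloid cells, differed by 3.89 ± 0.58 (SE). The other genes higher in Mpl by the rule were Prdm10, Ankrd28, Srd5a3, Tinagl1 and Agap1, at 3.83, 1.60, 2.12, 3.94 and 3.13. Other probe sets of Agap1, Ak1, Morrbid, Prdm10 and Dsg2 did not all point the same way (2 of 4, 1 of 2, 1 of 2, 2 of 3 and 5 of 6 were higher), and Agap1 was at -0.09 with its most variable probe set.

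The rule gave 12 genes lower in Mpl, Xist among them, none past the threshold. Ly6d, a marker of lymphoid progenitors biased to the B lineage, had a log2 fold change of -4.33 ± 0.51 (SE, limma adjusted p = 0.154), from 9.74 ± 0.97 in GFP to 5.41 ± 0.15 in Mpl (SD, n = 3 each). Mzb1, a chaperone of marginal zone B cells and plasma cells, was at -4.44 ± 0.73 (SE), and the lipid receptor gene Gpr18 at -4.69 ± 0.52 (SE). Tmem154 was at -3.52 ± 0.30 (SE, adjusted p = 0.133). The semaphorin receptor gene Plxnb2 was at -1.65 ± 0.24, Tbc1d10c at -1.84 ± 0.30 and the PIWI family gene Piwil4 at -5.78 ± 0.99 (SE). Clasrp, Rexo5, Maged2 and Ccdc61 were at -1.64, -1.61, -2.33 and -1.79, where 3 of 4 probe sets of Rexo5 and 1 of 2 of Maged2 were lower. Without GFP replicate 1, Tmem154, Xist and Gpr18 passed (adjusted p of 0.0496, 0.0244 and 0.0282).

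**Figure D1:**
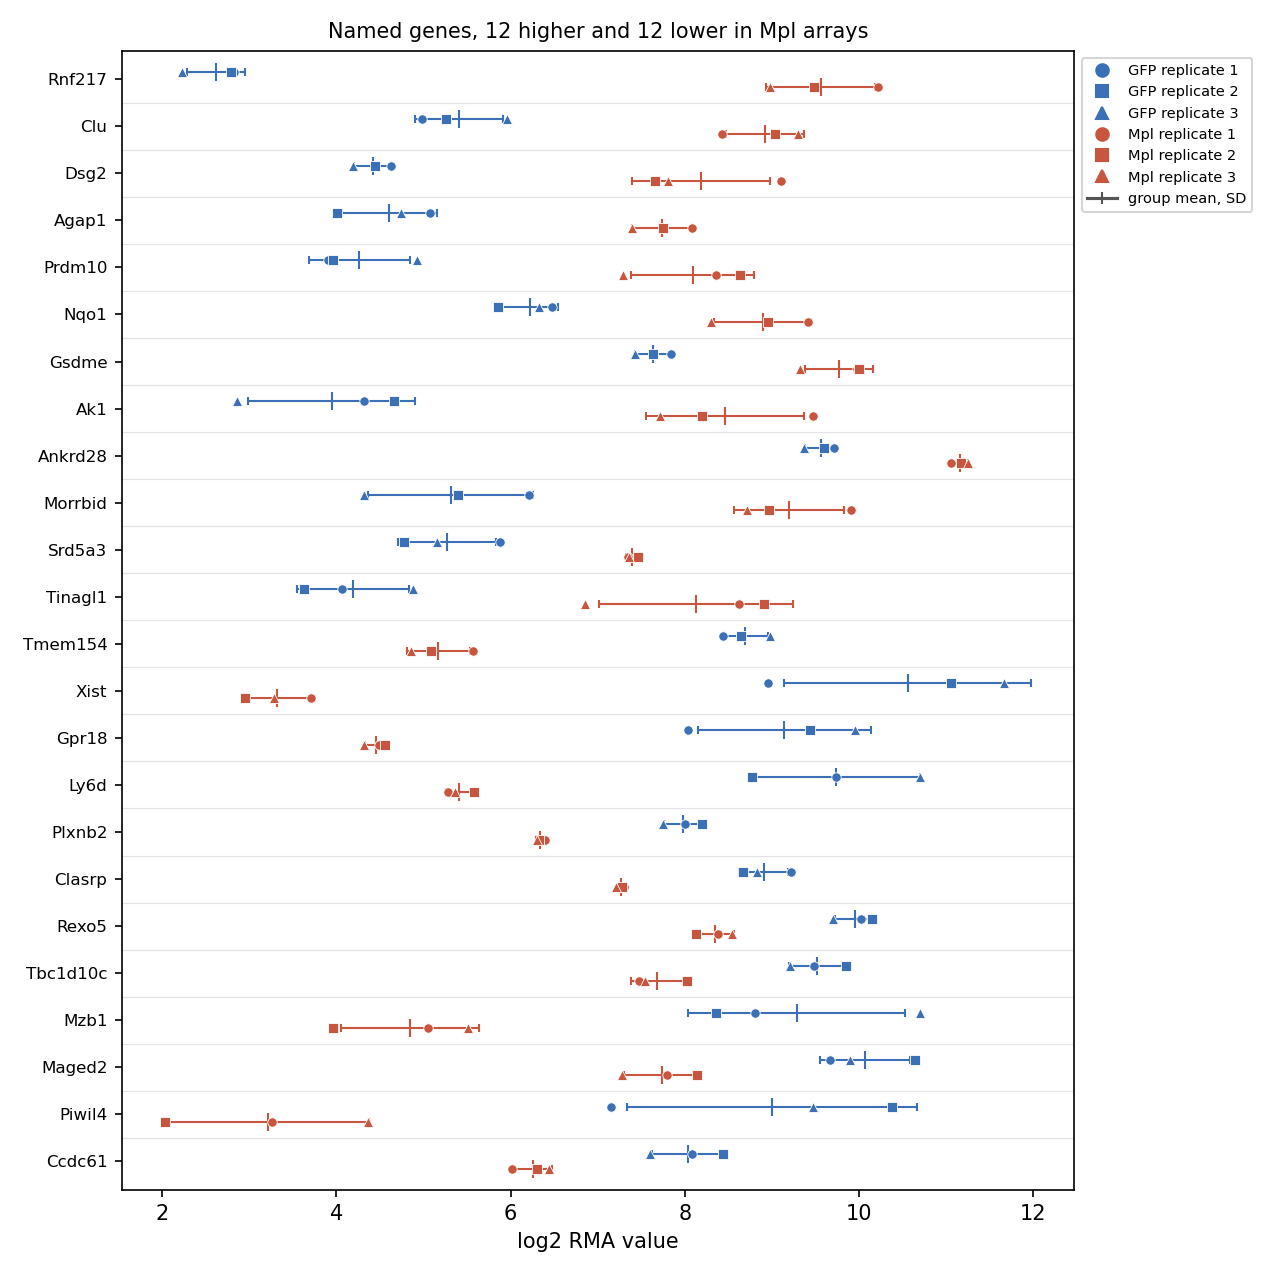
Log2 RMA value (horizontal axis) of the 24 named genes on each array, with GFP arrays in blue and Mpl arrays in red; the symbol gives the replicate, and the line and tick the group mean and SD (n = 3). The groups do not overlap for any of the 24 genes, which is how they were chosen, and Rnf217 is the gene past the threshold.

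Over all 18193 genes, 1 gene passed, and 2449 genes (13.5%) had an unadjusted limma p under 0.05, 677 higher and 1772 lower in Mpl. That count was 1398, 940 and 1208 without Mpl replicates 1, 2 and 3, and without GFP replicate 1 it was 3171, of which 1373 were higher. Groups did not overlap for 5188 genes, 28.5% against the 10% that chance gives for a gene when arrays are exchangeable. The array distributions themselves differed between groups, with lower quartiles of 2.87 to 3.18 on the GFP arrays and 2.70 to 2.81 on the Mpl arrays. The share was not counted for other splits of the arrays, so the excess does not measure an effect of the vector. Of 45037 probe sets, 0 passed at 0.05 with limma (lowest adjusted p = 0.0858), 24 at 0.10, and 5887 had an unadjusted p under 0.05. The median log2 fold change over all genes was -0.23, and it was -0.45 after subtraction of array medians, -0.16 after a further quantile normalization and -0.07 after cyclic loess. With those scalings the share of higher genes at an unadjusted p under 0.05 moved from 27.6% to 9.63%, 25.4% and 42.1%. Among genes at or above the median level the direction differed, with a median log2 fold change of 0.16, and the filter on low values left 337 higher and 336 lower genes at an unadjusted p under 0.05.

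Genes of long-term blood stem cells were higher in Mpl as a list. Of 34 measured members 29 were higher, with a median log2 fold change of 1.14, and the list shifted up against all other genes (camera adjusted p = 1.81e-07, but adjusted p = 0.517 with an estimated correlation). Clec1a, a C-type lectin gene, rose by 3.00 ± 0.53 (SE, adjusted p = 0.0485 adjusted over the list alone), from 2.38 to 5.38, where the GFP level lay below the arrays' lower quartiles. The LIM domain gene Fhl1 was at 4.42 ± 1.03, the aldehyde dehydrogenase gene Aldh1a1 at 1.78 ± 0.66 and the homeobox gene Hoxb5 at 2.92 ± 1.10 (SE), none of them past the threshold, and 1 of 2 probe sets of Fhl1 was higher. The list mean was 7.83, 6.05 and 7.47 on GFP replicates 1, 2 and 3 and 8.86, 8.71 and 7.79 on Mpl replicates 1, 2 and 3, so that Mpl replicate 3 lay below GFP replicate 1. With GFP replicates 2 and 3 both left out, where T and NK cell genes were high, the mean shift against other genes was 0.75 in place of 1.40 (adjusted p = 0.00474), and without GFP replicate 2 alone it was 0.89, with a median log2 fold change of 0.63.

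Cell cycle genes were higher on the Mpl arrays as lists. All 34 measured G2 and M phase genes were higher, with a median log2 fold change of 1.44 (camera adjusted p = 5.65e-10, adjusted p = 0.517 with an estimated correlation), and 30 of 32 S phase genes were higher with a median of 0.64 (camera adjusted p = 1.61e-06, adjusted p = 0.563 with an estimated correlation). No single member of either list passed, over all genes or adjusted over the list alone. The kinetochore gene Nuf2 was at 3.91 ± 1.10, the ubiquitin-conjugating enzyme gene Ube2c at 3.29 ± 1.09 and Anln, the gene of the cytokinesis protein anillin, at 2.25 ± 0.78 (SE). Blm, a DNA helicase gene, was at 1.58 ± 0.68 and Tipin, a replication fork gene, at 1.91 ± 0.86 (SE). GFP replicate 1 had a G2 and M phase mean of 9.17, beside 9.18 ± 0.51 in the Mpl group (SD, n = 3), and GFP replicates 2 and 3, on which T and NK cell genes were high, had 6.23 and 7.34. Leaving out both of those arrays ended the G2 and M phase call (mean shift against other genes 0.14 in place of 1.67, adjusted p = 0.112) and turned the S phase shift to -0.10 (adjusted p = 0.941). Leaving out GFP replicate 2 alone gave shifts of 1.01 and 0.34 and medians of 0.83 and 0.29. Without GFP replicate 1 the medians were 2.21 for G2 and M phase genes and 1.28 for S phase genes.

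Genes of energy metabolism and of the ribosome also shifted up as lists against all other genes. Of 29 oxidative phosphorylation genes 28 were higher, with a median log2 fold change of 0.63 (camera adjusted p = 1.01e-08, adjusted p = 0.517 with an estimated correlation). Of 23 hypoxia and glycolysis genes 15 were higher, with a median of 0.44 (camera adjusted p = 0.0029, adjusted p = 0.517 with an estimated correlation). Of 21 ribosomal protein genes 20 were higher, with a median of 0.16 (camera adjusted p = 0.0029, adjusted p = 0.563 with an estimated correlation), and that median was -0.05 after subtraction of array medians and -0.01 after cyclic loess. No member passed. The complex III gene Uqcrc2 was at 0.79 ± 0.28, the hexokinase gene Hk2 at 0.95 ± 0.30, and Rpl14 at 0.91 ± 0.36 (SE). The oxidative phosphorylation mean was 11.24 on GFP replicate 1 and 11.16 on Mpl replicate 1, and 10.56 on GFP replicate 2, and without GFP replicates 2 and 3 the mean shift against other genes was 0.30 in place of 0.63 (adjusted p = 0.00474). Without GFP replicate 2 the medians were 0.39 for oxidative phosphorylation genes, 0.22 for hypoxia and glycolysis genes and 0.08 for ribosomal protein genes, and without Mpl replicate 2 the hypoxia and glycolysis median was 0.26. Keeping only genes at or above the median level ended the hypoxia and glycolysis call and the ribosomal protein call (adjusted p of 0.149 and 0.182). The ribosomal protein call also ended after subtraction of array medians (adjusted p = 0.112), after cyclic loess (0.501 adjusted), without GFP replicates 2 and 3 (0.0711 adjusted) and with the T and NK level as a covariate (0.0808 adjusted).

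Lists of neutrophil, erythroid and megakaryocyte genes shifted up as well. Of 21 neutrophil and granule genes 17 were higher, with a median log2 fold change of 1.78 (camera adjusted p = 0.000517, adjusted p = 0.547 with an estimated correlation). Of 29 megakaryocyte and platelet genes, the lineage that thrombopoietin drives, 19 were higher with a median of 0.35 (camera adjusted p = 0.0166, adjusted p = 0.517 with an estimated correlation). Of 21 erythroid genes 15 were higher with a median of 0.91 (camera adjusted p = 0.0208, adjusted p = 0.588 with an estimated correlation). No member of these lists passed. Thbs1, which encodes the platelet granule protein thrombospondin 1, was at 4.25 ± 1.03, the caveolae gene Cavin2 at 3.79 ± 1.19, the granule gene Ngp at 3.34 ± 1.78 and the alpha globin gene Hba-a2 at 1.11 ± 0.39, while the heme synthesis gene Alas2 was at -1.96 ± 0.82 (SE). The neutrophil list mean was 5.93 on GFP replicate 2 and 8.78 and 9.19 on GFP replicates 1 and 3, and Mpo, the neutrophil myeloperoxidase gene, was at 4.08 on GFP replicate 2 and between 11.9 and 13.4 on the other arrays. Without GFP replicate 2 the neutrophil shift was 0.69 in place of 1.69 and its median 0.61, while the megakaryocyte median was 0.16 and the erythroid median 0.58. Without GFP replicates 2 and 3 the neutrophil median was 0.055 in place of 1.78 (shift of 0.94), and array weights gave a shift of 1.02. With the T and NK level as a covariate the neutrophil shift was 0.48 and the call ended (adjusted p = 0.163). GFP replicate 1 had the lowest megakaryocyte and erythroid means, 5.89 and 5.73, and without it both calls ended (mean shifts of 0.41 and 0.26 in place of 0.73 and 0.90, medians of 0.09 and 0.58, adjusted p of 0.252 and 0.474). With GFP replicates 2 and 3 both left out the megakaryocyte and erythroid shifts were 1.35 and 2.18, and with the T and NK level as a covariate 1.09 and 1.61. The erythroid call also ended without Mpl replicate 2 or 3 (shifts of 0.50 and 0.68, adjusted p of 0.152 and 0.0656), and the shift was 1.63 without GFP replicate 3 and 1.52 without Mpl replicate 1. Without GFP replicate 3 the megakaryocyte median was 0.67. Keeping only genes at or above the median level ended the erythroid and megakaryocyte calls (adjusted p of 0.143 and 0.063), and cyclic loess ended the erythroid call (adjusted p = 0.0501).

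Lymphoid genes fell as lists. Of 22 B cell genes 20 were lower in Mpl, with a median log2 fold change of -1.80 (camera adjusted p = 2.25e-06, adjusted p = 0.517 with an estimated correlation). Of those members, 10 fell when adjusted over the list alone and 0 over all genes. Jchain, the joining chain of secreted antibodies, fell by 2.35 ± 0.44, Cd79a and Cd79b, which carry the signal of the B cell receptor, fell by 3.53 ± 0.70 and 1.34 ± 0.35, and the immunoglobulin heavy chain gene Ighm fell by 3.07 ± 0.71 (SE; adjusted p of 0.0267, 0.0267, 0.0345 and 0.0345 over the list alone). The B cell mean was 6.22, 6.93 and 8.22 on GFP replicates 1, 2 and 3 and between 4.99 and 5.28 on the Mpl arrays. With GFP replicates 2 and 3 both left out the mean shift against other genes was -0.95 in place of -1.92 (adjusted p = 0.00267).

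Of 22 genes of multipotent and lymphoid-primed progenitors 19 were lower, with a median of -0.57 (camera adjusted p = 0.0391, adjusted p = 0.517 with an estimated correlation). Dntt, the terminal transferase of early lymphoid cells, fell by 1.72 ± 0.37 and the receptor gene Notch1 fell by 1.42 ± 0.31 (SE, adjusted p = 0.043 for both over the list alone). Ccr9, the receptor of thymus homing, was at -4.63 ± 1.30 and the chromatin organiser gene Satb1 at -1.28 ± 0.37 (SE). The list mean was 9.06, 9.09 and 9.65 on GFP replicates 1, 2 and 3 and 8.04, 8.39 and 7.87 on Mpl replicates 1, 2 and 3. The median was -1.08 without GFP replicate 2 and -0.98 without Mpl replicate 2. This call ended without GFP replicate 3, Mpl replicate 1 or Mpl replicate 3 (adjusted p of 0.273, 0.0546 and 0.0882) and with GFP replicates 2 and 3 both left out (adjusted p = 0.087). It also ended after subtraction of array medians (adjusted p = 0.0999), with the mean of all probe sets of a gene (0.0766 adjusted) and with the most variable probe set (0.188 adjusted), and passed in 10 of 17 alternatives with the preset correlation.

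Of 21 T and NK cell genes 20 were lower, with a median of -2.57 (camera adjusted p = 0.00695, adjusted p = 0.59 with an estimated correlation), and no member passed. The list mean was 4.80 on GFP replicate 1, 9.92 on GFP replicate 2 and 7.75 on GFP replicate 3, beside 4.94 ± 0.14 in the Mpl group (SD, n = 3). Cd3d, a chain of the T cell receptor complex, was at 3.73, 11.7 and 9.06 on GFP replicates 1, 2 and 3 and at 3.53 ± 0.36 in the Mpl group (SD, n = 3). Thy1 was at -3.21 ± 0.90, the interleukin receptor gene Il2rb at -4.98 ± 1.84 and the adhesion gene Cd2 at -5.14 ± 1.92 (SE), and Cd247 was at 2.21 with the probe set used and -3.95 with its most variable one. The call ended without GFP replicate 2 or GFP replicate 3 (shifts of -1.26 and -2.35 in place of -2.49, adjusted p of 0.112 and 0.0518). Its shift was -3.87 without GFP replicate 1. The median was -1.10 without GFP replicate 2 and -4.15 without GFP replicate 1. The mean shift turned to 0.27 with GFP replicates 2 and 3 both left out (adjusted p = 0.584). Subtraction of array medians also ended the call (adjusted p = 0.0667).

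**Figure D2:**
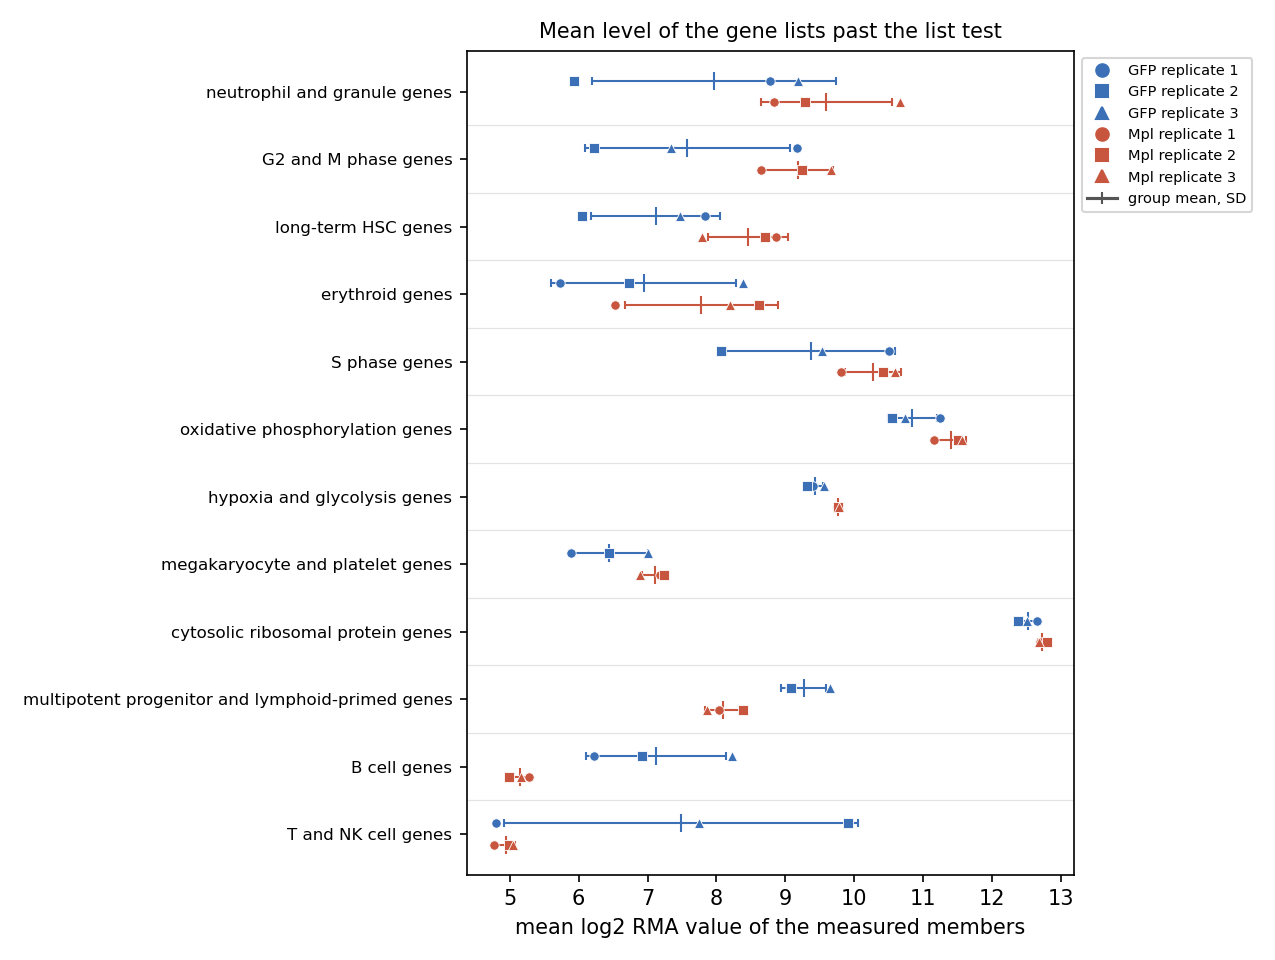
Mean log2 RMA value (horizontal axis) of the measured members of the 12 gene lists past the list test on each array, with GFP arrays in blue and Mpl arrays in red; the symbol gives the replicate, and the line and tick the group mean and SD (n = 3). The B cell and lymphoid-primed means of the 3 Mpl arrays lie below those of the 3 GFP arrays, and T and NK cell genes are high on GFP replicates 2 and 3 alone.

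With the estimated correlation 0 of the 24 lists passed with camera (lowest adjusted p = 0.517, with 1 list at an unadjusted p under 0.05). With fry's directional test 0 passed (lowest adjusted p = 0.248, with 3 lists at an unadjusted p under 0.05), so that none of the 12 calls held. Fry's mixed test, which asks for no shared direction, passed for B cell and lymphoid-primed genes (adjusted p = 0.0272 for both). It also passed for stromal genes (fry mixed adjusted p = 0.00042) and for no other list. The other 12 lists did not pass camera with the preset correlation. Immediate early genes came closest, with a median of -0.53 (adjusted p = 0.0753), and Ier5 was at -1.47 ± 0.39 and Zfp36, which encodes an mRNA decay factor, at -0.72 ± 0.23 (SE). The immediate early list passed in 9 of 17 alternatives with the preset correlation. It passed without GFP replicate 1 or Mpl replicate 3 (adjusted p of 0.000224 and 0.000743), with the filter on low values, a further quantile normalization, cyclic loess, trended and robust variance and the mean of all probe sets (adjusted p of 3.68e-05, 0.0235, 0.00044, 0.0129 and 0.0318), and with an upward shift of 0.42 without GFP replicates 2 and 3 (adjusted p = 0.0207). The rest of the 12 passed in 0 to 3 such alternatives each. The p53 target list passed without GFP replicate 3, without GFP replicates 2 and 3 and with the T and NK level as a covariate (adjusted p of 0.0208, 0.00267 and 0.0179), and the Hox list without Mpl replicate 3 and with cyclic loess (adjusted p of 0.0491 and 0.049). The interferon list passed with the filter and with cyclic loess (adjusted p of 0.00261 and 0.0223), and the stromal list with the filter (adjusted p = 0.0227). Quiescence, adhesion, inflammation and mast cell genes passed upward without GFP replicates 2 and 3 (adjusted p of 0.00113, 0.0157, 0.00113 and 0.00102) and with the T and NK level as a covariate (adjusted p of 0.00295, 0.0206, 0.00185 and 0.00142). Targets of STAT5 and cytokine feedback, which lie downstream of Mpl, had a median of -0.11 (adjusted p = 0.738). Among them the feedback inhibitor gene Socs2 was at 3.23 ± 1.44 and Id1 at 1.36 ± 0.47 (SE), and Socs2 was at 5.24 on GFP replicate 1 and between 9.53 and 12.2 on the other arrays. Medians were -0.52 for interferon response genes (adjusted p = 0.268), 0.28 for p53 targets (0.115 adjusted), 0.17 for Hox genes (0.115 adjusted), 0.20 for adhesion and niche receptor genes (0.144 adjusted), 0.27 for quiescence genes (0.247 adjusted) and -0.55 for fetal switch genes (0.266 adjusted). With arrays left out in turn the median ran from -0.078 (without GFP replicate 2) to 0.787 (without GFP replicate 3) for p53 targets. It turned to -0.15 for Hox genes without GFP replicate 2, to -0.058 for adhesion genes without Mpl replicate 1, and to -0.046 and -0.011 for quiescence genes without GFP replicate 1 or Mpl replicate 1. The fetal switch median ran from -0.78 (without Mpl replicate 1) to -0.28 (without GFP replicate 2). Monocyte and dendritic genes had -0.53, stromal and endothelial genes -0.50, mast cell genes -0.47 and inflammation genes -0.37 (adjusted p of 0.683, 0.383, 0.951 and 0.951). Camera gave the STAT5, mast cell and inflammation lists an upward direction while their medians and means were below 0. In the stromal list Lpl, the lipoprotein lipase gene, rose by 3.85 ± 0.29 (SE, adjusted p = 0.00027 over the list alone, 0.123 over all genes), with 1 of 2 probe sets higher and a GFP mean of 2.70, near background. Mast cell genes averaged 9.49 on GFP replicate 2, 6.45 on GFP replicate 1 and 7.23 on GFP replicate 3, and the shift of the mast cell list turned upward without GFP replicate 2 (0.60, adjusted p = 0.021).

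Among the genes that check samples, Xist, the noncoding RNA that silences an X chromosome in XX cells, was at 10.6 ± 1.42 in GFP and 3.32 ± 0.38 in Mpl (SD, n = 3 each), a log2 fold change of -7.24 ± 0.73 (SE, limma adjusted p = 0.133 over all genes). The group mean of Xist was lower in Mpl with each of 3 probe sets, although with one of them GFP replicate 1, at 5.93, lay below Mpl replicate 1, at 7.65. The Y-linked gene Eif2s3y was at 10.2, 10.5 and 7.37 on GFP replicates 1, 2 and 3 and at 10.5 ± 0.74 in the Mpl group (SD, n = 3). Kdm5d, also Y-linked, was at 2.79 on GFP replicate 2 and between 8.40 and 9.43 on the other arrays. The list of hemoglobin and mature blood RNA had a mean of 8.35 ± 1.21 in GFP and 9.01 ± 0.15 in Mpl (SD, n = 3 each). Of its members 5 were higher and 4 lower in Mpl. Among globin genes Hba-a2 was at 1.11, while the beta globin gene Hbb-b2 was at -1.33.

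**Figure D3:**
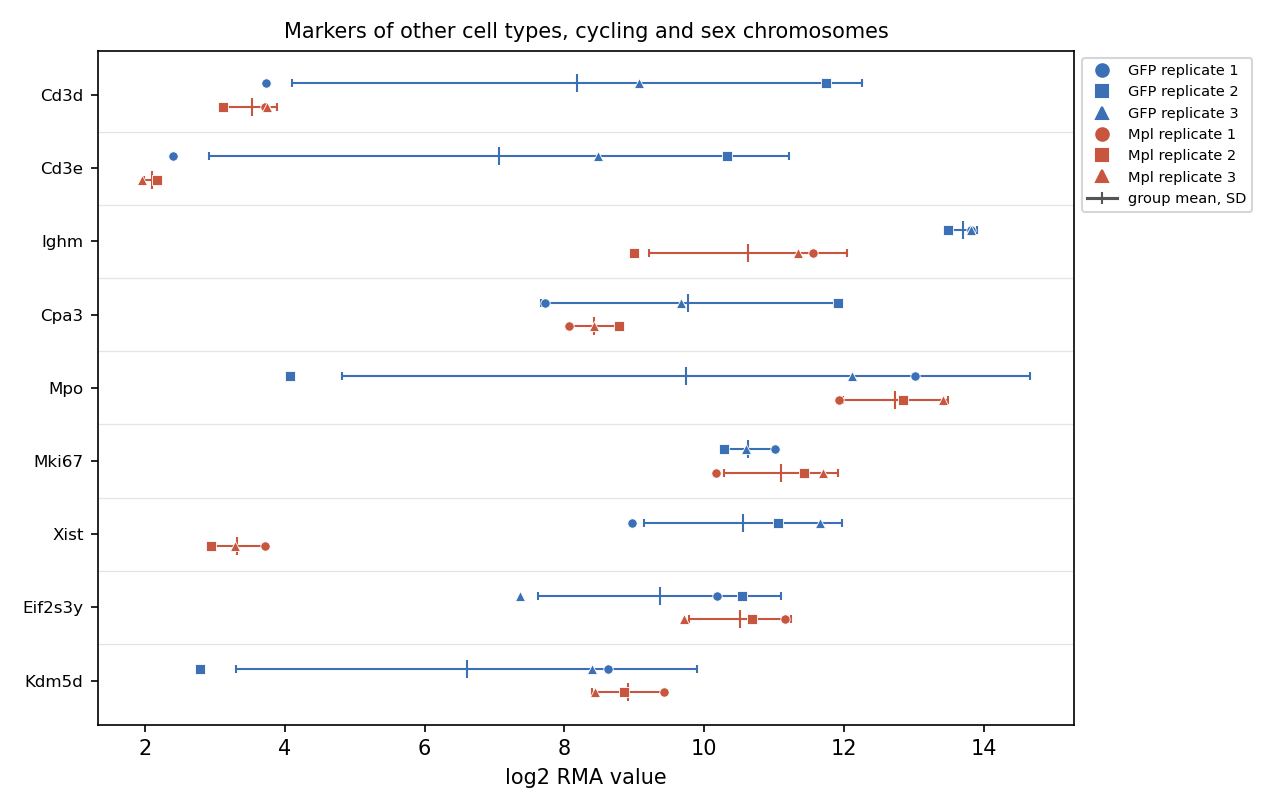
Log2 RMA value (horizontal axis) of markers of T cells (Cd3d, Cd3e), B cells (Ighm), mast cells (Cpa3), granulocyte precursors (Mpo) and cycling cells (Mki67), and of sex-linked genes (Xist, Eif2s3y, Kdm5d), on each array; GFP arrays are blue and Mpl arrays red, the symbol gives the replicate, and the line and tick the group mean and SD (n = 3). Cd3d and Cd3e are high on GFP replicates 2 and 3, Mpo is low on GFP replicate 2, and Xist is high on the 3 GFP arrays and low on the 3 Mpl arrays.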

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

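Leaving out GFP replicates 2 and 3 together and the T and NK covariate were chosen after the data were seen; the first leaves GFP replicate 1 as the lone control, assumed to vary like the Mpl arrays. Alternatives for the level of Mpl were not run, since no probe set carries that symbol, and the fetal switch list had too few genes under the filter on low values. Signal near background limits the folds of genes with low values, such as Rnf217 in GFP.

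Probe sets past the threshold numbered 0 under every alternative except the threshold of 0.10, which gave 24. For genes, the filter on low values, a further quantile normalization and the threshold of 0.10 gave 1, as reported. Subtracted array medians, cyclic loess, trended and robust variance, array weights, both other ways to represent a gene, the threshold of 0.01, the T and NK covariate and leaving out GFP replicates 2 and 3 together gave 0, and leaving out each array in turn gave 0 to 59 (59 without GFP replicate 1, 31 higher and 28 lower). Without GFP replicate 1 the only controls were GFP replicates 2 and 3, on which T and NK cell genes were high. The 28 lower genes then included Cd3e and Cd2 of the T and NK cell list and Blk and Ms4a1 of the B cell list. Rnf217 kept its direction in all 17 refits (log2 fold change 3.35 to 7.23, adjusted p 0.028 to 0.495) and passed in 3 of them. Gene lists past the threshold numbered 9 to 13 with the preset correlation, and 0 with an estimated correlation and 0 with fry's directional test. With GFP replicates 2 and 3 left out 13 lists passed, 7 of them among the 12 reported, and with the covariate 13, 8 of them among the 12. The causes of these changes were not tested.

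With the replicate number as a block 0 genes passed in place of 1, and 13 lists in place of 12, the added list being immediate early genes (adjusted p = 0.0309). Deviations of same-numbered arrays correlated at -0.091, -0.072 and -0.014, and no array correlated best with its own number. These values gave no sign that the numbers pair the arrays. With 3 arrays per group and no label on pairing, they cannot exclude it.

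Mean correlation over the more abundant probe sets alone was 0.644 within GFP and 0.901 within Mpl. Over all tested probe sets, with arrays left out in turn, the mean correlation ran from 0.80 to 0.886 within GFP and from 0.944 to 0.967 within Mpl.

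Over 19 alternatives the highest adjusted p of the 12 lists past the test ran from 0.517 to 0.941, and stem cell, B cell and oxidative phosphorylation genes passed in 17 of the 17 alternatives that kept the preset correlation. Of 503 list values under alternatives, 26 changed sign, 52 lost and 21 gained a call. As mean shifts against all other genes in log2 units, with GFP replicates 2 and 3 left out these were -0.16 for Hox genes, 0.27 for T and NK cell genes, 1.04 for mast cell genes, 0.11 for stromal genes, -0.10 for S phase genes, 0.37 for STAT5 targets, 0.42 for immediate early genes and 0.72 for inflammation genes. With the covariate they were -0.14 for Hox genes, 0.12 for T and NK cell genes (whose own mean is the covariate), 1.25 for mast cell genes, -0.14 for S phase genes, 0.23 for STAT5 targets, 0.30 for immediate early genes and 0.60 for inflammation genes. The filter on low values gave -0.055 for quiescence genes and -0.083 for adhesion genes, and array weights gave 0.33 for mast cell genes. With each array left out in turn the shift ran from -0.089 to 0.383 for quiescence genes, from -0.53 to 0.33 for monocyte genes, from -0.97 to 0.60 for mast cell genes, from -0.19 to 0.15 for STAT5 targets and from -0.88 to 0.040 for inflammation genes.

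Of 2215 values of 118 named genes under alternatives, 15 changed sign. With the most variable probe set the log2 fold change was -0.085 for Agap1, -3.95 for Cd247, 0.96 for Cxcl12, -0.42 for Tyms, -0.21 for Hif1a and -2.57 for Ndufb9. The mean of all probe sets gave -1.24 for Cd247, 0.36 for Cxcl12 and -0.48 for Ndufb9. Without GFP replicates 2 and 3 the values were -0.079 for Ms4a3, -0.78 for Elane and 0.70 for Cpa3, and the covariate gave 0.12 for Tpsab1 and 0.72 for Cpa3. Rpl27 was at -0.00024 after subtraction of array medians. The causes of these changes were not tested.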

Other observations

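Tests of the Xist pattern, of the cycling, stem cell and oxidative phosphorylation lists, and of other splits of the arrays were chosen after the results were seen; the 2 tests of the T and NK cell pattern were written down before their values were examined.

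Genes of erythroid and megakaryocyte cells stood lower on GFP replicate 1 than on the other GFP arrays. Vwf, the von Willebrand factor gene of megakaryocytes and some stem cells, was at 2.92 on GFP replicate 1 and between 8.22 and 9.08 on the other arrays, and Pf4, the platelet factor 4 gene, was at 5.35 and between 8.70 and 10.7. Both genes were named after their values were seen.

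T and NK cell genes were high on GFP replicates 2 and 3, although a lineage-negative sort would remove such cells. For uneven amplification of the RNA of both arrays, the share of other genes that were higher with them was counted. Of 17984 genes outside the cell type lists, 15.7% were higher on both than on the other 4 arrays (6.67% by chance). The bounds set beforehand, 50% and 20%, decide nothing, since RMA gives the arrays nearly 1 distribution. Genes in general cannot then lie higher on 2 of them. By the same measure 17 of 21 T and NK cell genes (81.0%), the list in which the pattern was found, were higher on both arrays. That these genes stood apart argues against amplification that raised genes without regard to cell type. Amplification that favoured these genes was not tested and stays open. The 3' minus 5' signal of Gapdh was 1.28, 1.95 and 1.30 on GFP replicates 1, 2 and 3 and 1.71, 0.945 and 0.834 on Mpl replicates 1, 2 and 3, and that of Actb 1.28, 1.39 and 1.05 and 1.77, 0.818 and 0.645. Lymphocytes among the sorted cells would raise further T and NK cell genes, and 46.9% of 32 such genes were higher on both arrays, short of the 50% set beforehand for this explanation and above the 20% set against it. Those with the highest log2 values on these arrays, which do not rank abundance between probe sets, were Gimap3 and Gimap6. Gimap3 was at 13.2 and 11.8 on these arrays and up to 9.56 elsewhere, and Gimap6 at 11.2 and 11.3 and up to 10.8 elsewhere. Of the 32, 16, none held by another list, lay above the array median on all Mpl arrays. That level is no detection call, so whether the sorted cells express these genes is not settled, and lymphocytes stay open. Further B and plasma cell genes gave 25% of 16 (11 above the median on all Mpl arrays), and further mast cell genes 0% of 13 (5 above it, 1 held by another list).

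Xist was high on the 3 GFP arrays and low on the 3 Mpl arrays. On GFP replicate 1 Xist lay 5.25 log2 units above the highest Mpl array while T and NK cell genes were at the Mpl level, but B cell genes averaged 6.22 there against at most 5.28 on the Mpl arrays, so lymphocytes from XX animals stay open. With another of the 3 Xist probe sets GFP replicate 1, at 5.93, lay below Mpl replicate 1, at 7.65. A candidate explanation is XX cells beside XY cells in the GFP samples, since 3 of 3 GFP arrays had both Xist and Eif2s3y above the array median. Other Y-linked genes were less even. Kdm5d was at 2.79 on GFP replicate 2, where the median gene was at 5.58, and at 8.62 and 8.40 on GFP replicates 1 and 3. Uty was at 4.93, 3.12 and 2.99 on GFP replicates 1, 2 and 3 with a probe set and at 6.26, 6.67 and 2.81 with another. The explanation was found from these values, the labels give no sex, and an effect of the Mpl vector itself was not tested, so these cannot be told apart. Were the groups to differ in XX cells, every gene and list difference reported here would carry that difference along with the vector.

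Cell cycle, stem cell and oxidative phosphorylation genes were higher in Mpl as lists with the preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.517 for G2 and M phase, stem cell and oxidative phosphorylation genes and 0.563 for S phase genes). Other cell types on GFP replicates 2 and 3 remain a candidate for the G2 and M phase shift of 1.67. That shift was 0.14 with both arrays left out and 0.28 with the T and NK level as a covariate. With the covariate the list still passed (camera adjusted p = 0.0206). The covariate was 4.80, 9.92 and 7.75 on GFP replicates 1, 2 and 3 and 4.78 to 5.05 on the Mpl arrays, so both fits rest largely on GFP replicate 1. They cannot separate other cell types from anything else that sets GFP replicates 2 and 3 apart. For long-term stem cell genes the shift was 0.75 and 0.57 in place of 1.40, and for oxidative phosphorylation genes 0.30 and 0.35 in place of 0.63, so that a part went with those arrays and a part did not. The bounds of this test were revised once after its values were seen: the first used the fit without both arrays alone, and by it the stem cell shift of 0.75 would have counted against this explanation. With 1 control array left, the remainder and an effect of the Mpl vector cannot be told apart for these 2 lists.

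The 6 arrays have 10 splits into groups of 3, too few for a share under 0.05. For probe sets the real split gave 0 and the highest other split 0, so all 10 splits gave as many. For genes the real split gave 1 and the highest other 0, and 1 of the 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 2449 genes and the highest other 1191. For gene lists the real split gave 12 and the highest other 12, and 3 of the 10 splits gave as many. The other splits with 12 kept GFP replicates 2 and 3 in 1 group, and another such split gave 9. Splits that put these arrays in different groups gave 4 to 9.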
